A study of Mus musculus with 5 samples.

How the data were processed

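Single cells of mouse organoids, cultures of gut epithelium grown in 3 dimensions, were profiled by SORT-seq, a plate method in which sorted cells are lysed in wells holding barcoded primers. Per the labels' protocols, organoids of the small intestine were grown with Egf, R-spondin and Noggin, broken into single cells, sorted by flow cytometry into 384-well plates and made into libraries with the CEL-Seq2 chemistry, which reads a tag near the 3' end of each transcript. The 5 libraries were 1 plate each. They were fetal intestinal organoids of wild-type genotype (fetal), small intestinal organoids of wild-type genotype (WT), of genotype Lkb1 +/- (het), and 2 libraries of genotype Lkb1 -/- whose titles carry the marks Bud and Cys. Neither mark is explained in the labels, so both are used as given and the libraries were treated as 2 groups of 1, not as replicates.

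For each library the authors deposited 3 tables of genes by wells. The table of unique molecular identifiers (UMIs) holds raw counts, deposited as whole numbers with no normalization, and was the basis of every value in the text. The table of reads, also raw counts as deposited, served only for the number of reads per UMI. The deposited transcript table holds estimated counts: its values equalled the UMI counts corrected for the 4096 codes that a 6-base identifier allows, with a largest absolute deviation of 3.638e-12 over the wells tested, and it was used as an alternative. The submitters' processing notes name STAR 2.6.1, featureCounts 1.5.2, Seurat 4.1.0 and the genome build GRCm38. The handling of strand and of reads that match several genes is not given in the sources used here, so values of near-identical gene families, the defensins (Defa) and other paralogs among them, and of overlapping genes are uncertain. The tables held no mitochondrial genes.

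Wells with at least 1000 UMIs from nuclear genes, spike-ins left out, were kept. The planned cap of 30% mitochondrial UMIs had nothing to act on. No doublet caller was run because the wells held sorted single cells; wells with very many UMIs are reported instead. UMIs were summed over the kept wells of a library and scaled by the library total over nuclear genes to CPM, the usual unit of scaled counts. A gene was measured in a comparison when it had at least 10 UMIs over both libraries. It was called higher or lower when the ratio of CPM was at least 1.5 in that direction and its exact conditional binomial 95% interval excluded 1. Levels have exact Poisson intervals and shares of cells exact binomial (Clopper-Pearson) intervals, while a share of 0 has an upper limit of 3 counts of the total, which limits cells with a UMI and not cells that express the gene. All intervals cover counting error only, since molecules of one well are not independent draws from a culture and nothing measures the spread between cultures. With 1 library per group there were no replicates. No test of genotype was made, since the titles mark the 2 Lkb1 -/- libraries apart and they were kept as groups of their own, and no p-value is given. Log2 ratios were taken after adding 10 CPM to both values, which understates the difference for low genes. Where a gene had no UMI in one library, its fold is a bound against a floor of 3 UMIs in that library.

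The 5 comparisons were Bud, Cys, het and fetal each against WT, and Cys against Bud. In each, 31 gene lists were examined: intestinal stem cell, S phase, G2 and M phase, enterocyte, Paneth, goblet, enteroendocrine, tuft, M cell, secretory progenitor, fetal and regenerative gut epithelium, YAP/TAZ targets, gastric epithelium, intestinal identity, WNT targets, the LKB1 complex and its kinases, CREB/CRTC targets, ERK targets, glycolysis, oxidative phosphorylation, cholesterol synthesis, interferon response, MHC class II, epithelial defence, p53 targets, hypoxia, unfolded protein response, dissociation stress, and immune, mesenchymal and endothelial cells. Some genes belong to several lists. The median log2 ratio of a list was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Random genes were drawn independently, whereas members of a list can vary together in the same few cells, so a percentile does not measure the strength of evidence. A second median, with genes at 0 in one library placed at their bound and no CPM added, is given for some lists as the median at the bound.

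The named genes followed a fixed rule. Per comparison it took the 10 largest and 10 smallest log2 ratios among genes with a UMI in at least 10% of the kept cells of the higher library, leaving out mitochondrial, ribosomal protein, predicted (Gm and a number), Rik and spike-in genes. It also took the 10 genes each way with the largest gap between both Lkb1 -/- libraries and both the WT and het libraries, up to 4 members of each list with the largest absolute log2 ratio and at least 20 CPM in either library, Stk11, and 16 canonical markers whatever their values. Other list members are named where they account for a list's count, and were chosen after their values were seen. Some named genes are not reported here. The share of a gene's UMIs held by its single largest cell was computed for the named genes.

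All kept cells were clustered together with scanpy 1.11.5 after scaling each cell to 10000 UMIs, log transformation and selection of 2000 variable genes, with 20 principal components, 15 neighbours and Leiden resolution 1.0, without batch integration. Clusters were named after fixed marker lists when at least 2 markers of a list were among the 10 leading genes, a threshold set after the clusters were seen. It left 8 of the 16 clusters unnamed, of which clusters 0 and 6 had 1 marker among their leading genes and the others none. Cluster 6 held 22.8% of WT, 8.55% of het and 24.8% of Bud cells, and cluster 0 held 39.9% of fetal cells. Shares of cells with a UMI of a marker were taken after thinning every cell to 1000 UMIs and also without thinning. Similarity to fetal organoids was the correlation across 7165 genes, with a mean of at least 20 CPM over the libraries, between the log2 ratio of fetal over WT and that of Bud or Cys over het, a pairing in which the 2 ratios share no library. Genes are not independent replicates, so this correlation has no p-value.

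The groups, the comparisons, the thresholds, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The alternatives fixed then were UMI minimums of 500 and 3000 per well, the deposited transcript counts, median-of-ratios scaling over the 5 libraries, equal weight for every cell, no minimum or a minimum of 50 UMIs for a measured gene, 1 CPM added in place of 10, other settings of the fetal comparison, other cluster resolutions (0.5 and 1.5), clustering without cell cycle genes, and other thinning depths. After seeing the data, further alternatives left out wells above 100000 UMIs, left out wells with over 2% of UMIs from Kcnq1ot1, a nuclear RNA whose share rises in damaged cells, and took het as the reference for Bud and Cys. Median-of-ratios scaling moved log2 ratios against WT by at most 0.0982.

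The rule for calling genes was tested on simulated counts with Poisson error only, drawn from the WT profile of 9827 genes and the totals of the Bud and WT libraries. It called 12.0% of 50 genes planted at 1.25-fold, 100% of 50 at 2-fold, 100% of 50 at 4-fold, 94.0% of 50 planted at 0.5-fold, and 1.03% of 9627 unchanged genes. The simulation had no spread between cells or cultures, so these rates cover counting error only and do not give the rate of false calls in the real libraries. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.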

Results

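The transcriptomes of single organoid cells were measured in 5 libraries, 1 per group and each from a 384-well plate, to compare small intestinal organoids with both, 1 or no intact copies of Lkb1 and to set them beside fetal intestinal organoids. LKB1 is the protein kinase encoded by Stk11 that switches on AMPK and related kinases. After filtering, 371 fetal, 302 WT, 351 het, 318 Bud and 359 Cys cells remained, with 5865507, 4035219, 4395349, 4199196 and 4981282 UMIs in all. The median cell held 14637 UMIs and 4538 genes in the fetal library, 12287.5 and 3949.5 in WT, 11503 and 3703 in het, 11385 and 3626 in Bud, and 10414 and 3418 in Cys. There were 2.55 (WT) to 3.29 (Bud) reads per UMI. No group had a replicate, so each comparison describes the libraries compared, and the intervals in brackets are 95% counting intervals that cover counting error only.

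The plates differed in quality. Wells with over 2% of UMIs from Kcnq1ot1, often used as a sign of damaged cells in this method, made up 0.539% of fetal, 7.28% of WT, 17.1% of het, 13.5% of Bud and 6.13% of Cys wells. A pair of Cys wells held 452137 and 147615 UMIs of the 4981282 in that library, whereas the largest well of the other libraries held 82879 (fetal). The ribosomal RNA precursor Rn45s took 6.36% of Cys UMIs and 2.71% to 3.50% of those of the other libraries. Leaving out either kind of well, an alternative chosen after seeing the data, left every one of the 204 log2 ratios of named genes within its counting interval. Both very large wells were in Cys, so leaving them out could not change a ratio between other libraries. Some list results did move, by the limits given below for the alternatives. Without the large wells, 8 list counts moved and 302 did not, and 5 list medians moved and 131 did not. Without the wells rich in Kcnq1ot1, 11 list counts moved and 299 did not, and 4 list medians moved and 132 did not.

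Stk11 (chromosome 10, 80115803 to 80130682, forward strand, GRCm38) was read at 20.6 CPM in WT (16.4 to 25.5), 14.1 in het (10.8 to 18.1), 11.7 in Bud (8.63 to 15.4), 9.03 in Cys (6.59 to 12.1) and 16.0 in fetal organoids (13.0 to 19.6). The ratio to WT was 0.686 in het (0.485 to 0.964) and 0.567 in Bud (0.390 to 0.817), and Cys was 2.28-fold lower (1.57 to 3.35). Bud and Cys met the rule for a lower gene and het did not. The edited part of the gene is not given in the labels and the chemistry reads only a 3' tag, so transcripts that no longer encode the kinase may still be counted, and these levels do not check the genotypes. Of 20 measured members of the LKB1 complex and its kinases, Stk11, Strada and Sik3 were lower in Bud (list median log2 ratio 0.05, percentile 91.8).

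Bud organoids were lower than WT in genes of the absorptive cells of the gut and higher in genes of the fetal and regenerating epithelium, of goblet and Paneth cells and in CREB/CRTC targets. Of 17 measured enterocyte genes, 16 were lower and none higher (median log2 ratio -1.38, median at the bound -1.91, percentile 0). Of 15 fetal and regenerative genes, 11 were higher and none lower (median 0.51, percentile 100). Stem cell and proliferation genes differed little: Lgr5, the receptor that marks intestinal stem cells, stood at 309.8 CPM in Bud and 278 in WT, and the proliferation marker Mki67 at 194.6 and 195.0.

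The fatty acid binding protein Fabp1 was 1.67 CPM in Bud against 615 in WT, 369-fold lower (179 to 918). The retinol carrier Rbp2 was 37.8-fold lower, the lipoprotein components Apoa4 and Apoc3 18.2-fold and 14.1-fold lower, and the alcohol dehydrogenase Adh1 19.1-fold lower (15.3 to 24.2), with 61.0% of its Bud UMIs in 1 cell. The brush border phosphatase Alpi was 15.2 CPM against 77.6, with 40.6% of its Bud UMIs in 1 cell. Other large differences lay outside the enterocyte list. The chloride channel family member Clic6 had no UMI in Bud against 127 CPM in WT, at least 178-fold lower, Fam111a was 127-fold lower (54.0 to 392), and the interferon-induced membrane protein Ifitm3 was 0.714 CPM against 243. The RNA-binding protein Igf2bp3 was 46.1-fold lower, and the mucosal glycoprotein Dmbt1 was 3.52-fold lower. Against het, a reference chosen after seeing the data, the log2 ratios of Ifitm3 and Igf2bp3 were only 0.0043 and 0.16.

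Among the fetal and regenerative genes, the annexin Anxa1 was 115 CPM in Bud and 8.18 in WT, 14.1-fold higher (9.92 to 20.8), with 24.1% of its Bud UMIs in 1 cell. The calcium-binding protein S100a6 was 3.82-fold higher (3.42 to 4.27), the alarmin Il33 11.1-fold (5.38 to 26.4) and Anxa3 5.97-fold (3.83 to 9.73). Markers most often used for the fetal state were low: Clu stood at 11.7 CPM against 10.4, Ly6a at 17.4 against 10.9 with 31.5% of its Bud UMIs in 1 cell, and Spp1 had no UMI in either library. Outside the lists, the secreted phospholipase Pla2g2a was 74.1-fold higher (43.1 to 139.6) at 239 CPM, the folate hydrolase Ggh 11.5-fold higher (8.79 to 15.4), Reg4 16.9-fold higher (11.2 to 26.6), with 29.7% of its Bud UMIs in 1 cell, and Erdr1 56.5-fold higher (35.6 to 95.8), though its log2 ratio of 4.18 to WT was only 0.57 against het. Pla2g2a is annotated as a polymorphic pseudogene, a gene disrupted in some genomes and intact in others, and the labels do not say whether the lines share an origin. Cd44, a hyaluronan receptor of the stem cell list, was 2.29-fold higher (2.08 to 2.52) and the only 1 of 14 stem cell genes called (median 0.04, percentile 79.7).

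Secretory genes were mixed in Bud. Of 14 goblet genes, 8 were higher and 1 lower (median 0.53, percentile 100): the trefoil peptide Tff3 was 1221 CPM against 641, Spink4 2.39-fold higher (2.16 to 2.65), and the gel-forming mucin Muc2 1.67-fold higher (1.44 to 1.94), although 1 cell held 81.7% of its Bud UMIs and 77.4% of its WT UMIs. Of 6 Paneth genes, 4 were higher and 1 lower (median 0.64), with Ang4 at 49.3 CPM against 9.42 and 48.3% of its Bud UMIs in 1 cell, and the lysozyme Lyz1 at 155 CPM against 106, not called. Of 9 secretory progenitor genes, 5 were higher (median 0.46), among them Neurog3, the factor that starts endocrine differentiation, at 128 CPM against 82.3. In contrast, 8 of 12 enteroendocrine genes were lower and 2 higher (median -0.75, median at the bound -3.25, percentile 0). The granins Chga and Chgb, the serotonin enzyme Tph1 and the factor Fev had no UMI in Bud, at least 18.7-, 155-, 51.7- and 35.4-fold lower, though 1 WT cell held 91.5% of the Chgb UMIs, 60.4% of the Tph1 UMIs and 59.3% of the Chga UMIs. Ghrelin (Ghrl) was 70.0 CPM in Bud with no UMI in WT, and 62.6% of it lay in 1 cell. Tuft genes were lower in 3 of 7 (median -0.24) and the M cell gene Ccl20 was the only 1 of 3 called, higher.

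Of 12 CREB/CRTC targets, genes driven by coactivators that LKB1-dependent kinases hold back, 6 were higher and none lower in Bud (median 0.34, percentile 99.99). The nuclear receptor Nr4a1 was 47.9 CPM against 4.71, 10.2-fold higher (6.34 to 17.2), and Fos was 3.67-fold higher (3.11 to 4.34). Of 12 dissociation stress genes, 5 were higher (Fos, Junb, Egr1, Atf3 and Hspa1b) and 1 lower (median 0.31), and Fos and Atf3 were among the higher genes of both lists. ERK targets were higher in 4 of 14 (median 0.12), with Phlda1 at 568 CPM against 306. Among p53 targets 4 of 13 were higher (median 0.13), as were 5 of 10 epithelial defence genes, of which 2 were lower (median 0.25), and 2 of 14 genes of the unfolded protein response (median 0.16). Of 14 YAP/TAZ targets, 2 were higher and 3 lower (median 0.10). Cholesterol synthesis was lower in 3 of 15 genes (median -0.35, percentile 0), with the sterol sensor Insig1 at 51.0 CPM against 117. S phase genes were lower in 2 of 16 (median -0.15) and G2 and M phase genes in 1 of 16 (median -0.18). WNT targets (2 higher and 2 lower of 13, median 0.01), intestinal identity (1 and 1 of 13, median -0.08), glycolysis (1 and 1 of 15, median -0.05), hypoxia (1 and 2 of 12, median -0.05), oxidative phosphorylation (none of 17, median 0.03) and interferon genes (1 lower of 9, median -0.12) had few calls. Among gastric genes 4 of 5 were higher (median 0.66), all at low levels, such as the annexin Anxa10 at 9.29 CPM against 2.23 and the trefoil peptide Tff1 at 2.62 against 0.248.

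Which library served as reference mattered for Bud. Against het, chosen after seeing the data, 7 rather than 11 fetal and regenerative genes were higher and 1, Anxa5, lower, with the median of 0.18 inside the range of random lists (percentile 97.3), 4 rather than 6 CREB/CRTC targets were higher with a median of 0.17 at the edge of that range (percentile 97.52), the medians of the Paneth, goblet, M cell, ERK, YAP/TAZ, LKB1 complex, epithelial defence and dissociation stress lists turned negative, and those of S phase, glycolysis and hypoxia turned positive. The gastric median was -0.29 when 50 UMIs were required of a gene, which left out low genes such as Tff1, so it does not describe the whole list. With equal weight for every cell the Paneth median was 1.44 and the log2 ratios of Muc2 and Lyz1 were 1.40 and 1.44, against 0.66 and 0.51 in the summed counts.

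**Figure D1:**
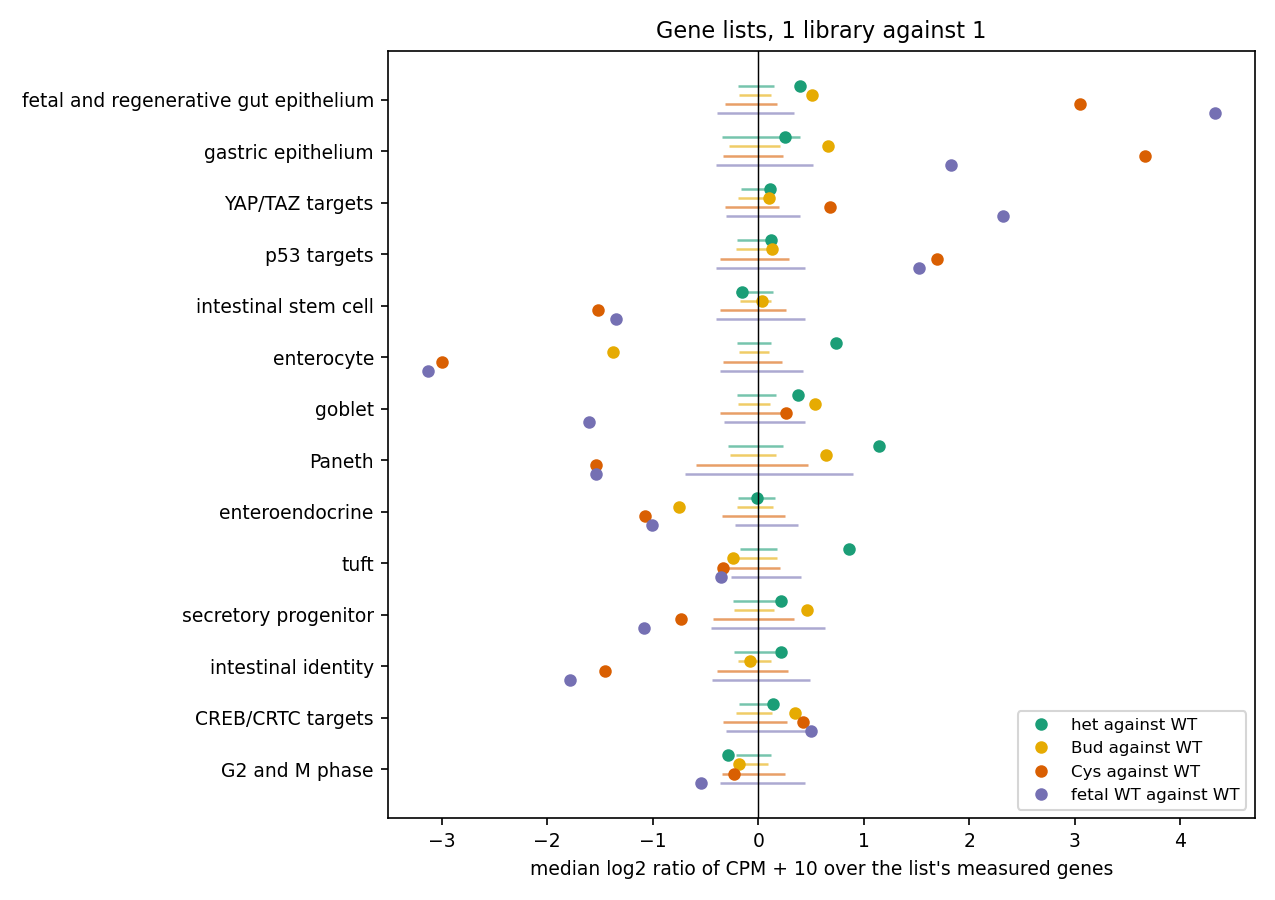
Median log2 ratio of CPM (10 CPM added) of 14 gene lists in the het, Bud, Cys and fetal libraries against WT, 1 point per library, with horizontal lines for the range that held the middle 95% of random lists matched on expression. The fetal and regenerative list lay at 3.05 in Cys and 4.33 in fetal organoids against 0.51 in Bud.

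In Cys organoids, fetal, gastric and p53 target genes were higher than in WT, and genes of intestinal stem cells, enterocytes and intestinal identity were lower. All 20 fetal and regenerative genes were higher (median log2 ratio 3.05, median at the bound 4.38, percentile 100), as were 11 of 12 gastric genes (median 3.67, at the bound 6.69, percentile 100), with the pepsinogen Pgc lower. Of 14 stem cell genes, 10 were lower and 2 higher (median -1.52, percentile 0), and 16 of 17 enterocyte genes were lower (median -2.99, at the bound -6.84, percentile 0). Mki67, at 213 CPM against 195, was not called.

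The secreted chaperone Clu was 3399 CPM in Cys and 10.4 in WT, 327-fold higher (241 to 453). Anxa1 was 131-fold (93.4 to 191), Il33 766-fold, the stem cell antigen Ly6a 46.6-fold (34.6 to 64.3) and S100a6 28.2-fold higher (25.6 to 31.3). Mesothelin (Msln) reached 1808 CPM with no UMI in WT, at least 2432-fold higher, while Spp1 reached only 2.21 CPM. Among gastric genes, the trefoil peptides Tff1 and Tff2 stood at 3421 and 425 CPM against 0.248 and 0.496, and the stomach secretory protein Gkn1 at 538 against 0.248. The gastric gene Vsig1 reached 324 CPM and Anxa10 252, against 0 and 2.23 in WT. Lactotransferrin (Ltf) at 603.5 CPM and Dpcr1 at 602.5 were near or at 0 in WT. After thinning to 1000 UMIs, 78.3% of Cys cells had a UMI of Tff1 and 90.5% one of Clu, against 0% and 1.66% of WT cells (0 of 302 cells allows up to 0.993% of cells with a UMI after thinning). Without thinning, the shares were 98.6% and 98.9% in Cys and 0.331% and 7.28% in WT.

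Intestinal identity was lower in 7 of 13 genes and higher in 1, Klf5 (median -1.45, percentile 0). The homeobox factors Cdx1 and Cdx2, which set intestinal fate, were 134-fold (67.7 to 311) and 4.51-fold lower (3.27 to 6.32), the cadherin Cdh17 19.3-fold and Isx 175-fold lower. Lgr5 was 13.1 CPM against 278, 21.3-fold lower (16.6 to 27.8), the stem cell matrix protein Smoc2 173-fold (90.6 to 378) and Axin2 16.3-fold lower, whereas Gkn3 was 10.3-fold and Cd44 2.82-fold higher. WNT targets were lower in 7 of 12 and higher in 1 (median -0.59). Fabp1 was 340-fold and the disaccharidase Sis 172-fold lower, and outside the lists the chloride channel regulator Clca4 was 60.3-fold, the gut chemokine Ccl25 73.4-fold and Lypd8 40.0-fold lower. Paneth genes were lower in 4 of 5 (median -1.54), with Lyz1 40.7-fold lower, as were all 11 enteroendocrine genes (median -1.07) and 5 of 8 secretory progenitor genes, of which 2 were higher (median -0.74). For Chga, Chgb and Tph1, most of the WT UMIs lay in a single cell. Neurog3 was 0.602 CPM against 82.3. Goblet genes split, 7 higher and 7 lower of 14 (median 0.26): the transcription factor Spdef and the stress sensor Ern2 were 17.3-fold and 13.6-fold higher, while Muc2 was 11.3-fold and Fcgbp 24.1-fold lower. Most of the WT Muc2 UMIs lay in a single cell. Tuft genes were higher in 2 and lower in 5 of 8 (median -0.33), with the actin-binding protein Avil at 40.8 CPM against 3.72, and 2 of 3 M cell genes were higher (median 0.37).

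Of 13 p53 targets, 12 were higher in Cys (median 1.69, percentile 100). The receptor Eda2r was 74.5 CPM against 0.496, Zmat3 8.74-fold, Phlda3 10.3-fold and cyclin G1 (Ccng1) 5.62-fold higher. YAP/TAZ targets were higher in 10 of 17 and lower in 2 (median 0.68, percentile 100), with the matricellular protein Ctgf at 771 CPM against 2.23, Myof 51.6-fold higher, and Ankrd1 at 28.1 CPM against 0.248 with 40.7% of its Cys UMIs in 1 cell. CREB/CRTC targets were higher in 8 of 12 and lower in 1 (median 0.43), among them Nr4a1 at 11.4-fold, the phosphodiesterase Pde4d at 8.24-fold and amphiregulin (Areg) at 9.40-fold. ERK targets were higher in 5 of 14 and lower in 1 (median 0.16). The LKB1 complex and its kinases had 5 higher and 2 lower of 20 (median -0.05). The unfolded protein response had 6 higher and 2 lower of 14 (median 0.44), epithelial defence 5 and 2 of 9 (median 0.37), dissociation stress 5 and 3 of 13 (median 0.05), glycolysis 2 and 1 of 15 (median 0.12), cholesterol synthesis 1 and 3 of 15 (median -0.30) and interferon genes 2 and 1 of 8 (median -0.19). Hypoxia genes split 4 and 4 of 12 (median 0.15), with the carbonic anhydrase Car9 at 39.7 CPM against 446. Oxidative phosphorylation was lower in 5 of 17 genes (median -0.44), S phase in 4 of 16 (median -0.41) and G2 and M phase in 3 of 16 (median -0.23).

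With het as reference, chosen after seeing the data, the goblet, epithelial defence, dissociation stress, ERK, S phase and G2 and M phase medians of Cys changed sign. When 50 UMIs were required, the tuft median was 1.89, but this equalled the log2 ratio of Avil and does not describe the list. Over 10 alternatives, 17 to 20 fetal and regenerative genes, 9 to 11 gastric genes and 10 to 13 p53 targets were higher in Cys, and with equal weight for every cell the log2 ratio of Lypd8 was -3.84 in place of -4.84.

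**Figure D2:**
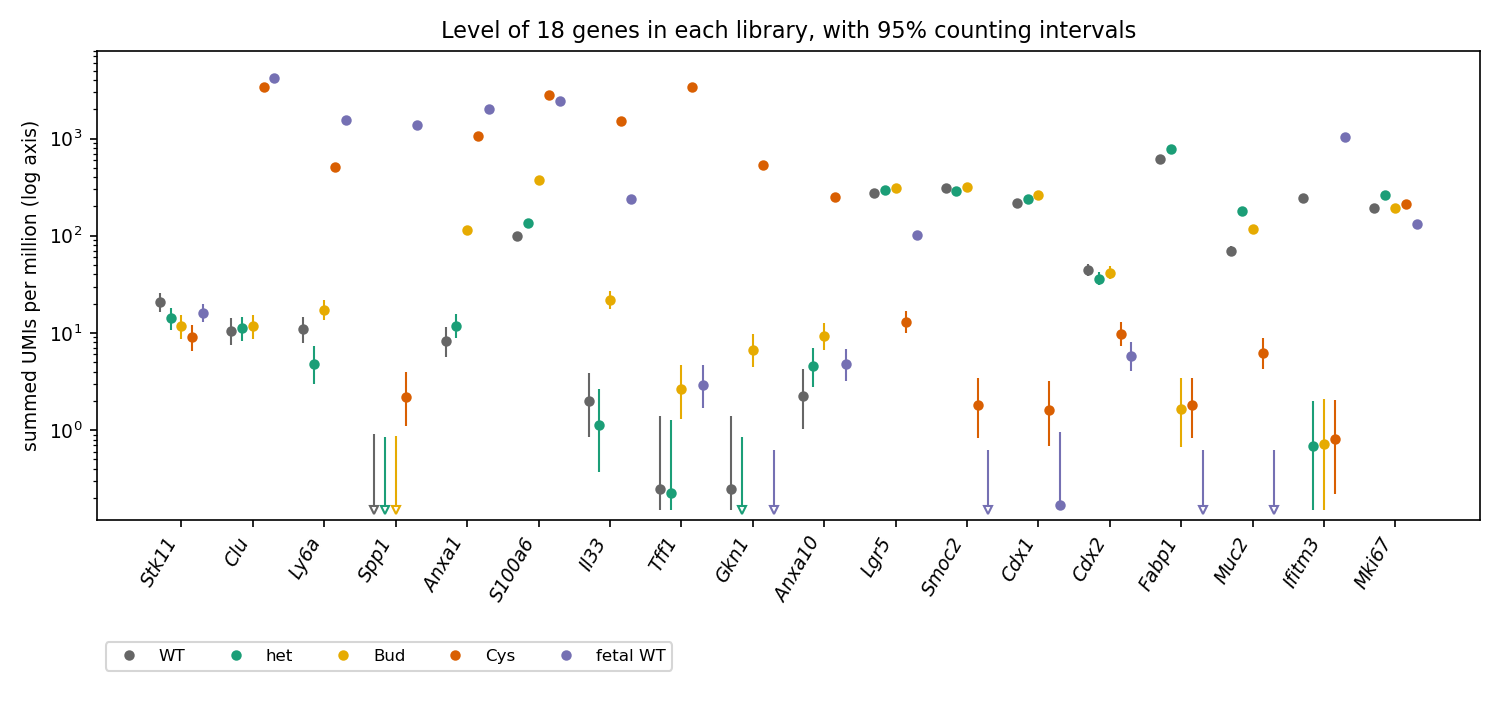
Levels of 18 genes in CPM on a log axis, 1 point per library with its 95% counting interval, and open triangles at the foot of the axis for genes with 0 UMIs. Clu stood at 3399 CPM in Cys and 4158 in fetal organoids against 10.4 in WT, and Tff1 at 3421 in Cys against 2.90 in fetal organoids.

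The 2 Lkb1 -/- libraries were also set against each other. Of 20 fetal and regenerative genes, 18 were higher in Cys than in Bud, with Cldn4 and Emp1 not called (median log2 ratio 2.57, percentile 100), as were 11 of 12 gastric genes (median 3.38), 11 of 13 p53 targets (median 1.52) and 10 of 16 YAP/TAZ targets (median 0.76). Lower in Cys were 9 of 14 stem cell genes (median -1.37), 13 of 15 enterocyte genes (median -1.20), 5 of 6 Paneth genes (median -2.04) and 7 of 13 intestinal identity genes (median -1.32). Clu was 291-fold higher (220.2 to 394), Il33 69.3-fold (56.4 to 86.1), Ctgf 108-fold and the carbonic anhydrase Car2 321-fold higher (194 to 574), whereas Lgr5 was 23.7-fold (18.5 to 30.9), Muc2 18.8-fold and Cdx1 163-fold lower. Most of the Bud Muc2 UMIs lay in a single cell. Pla2g2a had no UMI in Cys, at least 396-fold lower, and the tight junction gene Cldn15 was 0.201 CPM against 219. CREB/CRTC targets split, 3 higher and 4 lower of 12 (median 0.13): Nr4a1 stood at 53.8 CPM in Cys and 47.9 in Bud (ratio 1.12, 0.933 to 1.36), not called, and Fos was 1.58-fold lower in Cys. Goblet genes split 7 and 7 of 14 (median -0.53). With no minimum count the Paneth median was -1.09 and the gastric median 2.54, and the enterocyte median was -1.93 with 50 UMIs required.

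By a size rule with no test, 10 genes each way showed the largest gap between both Lkb1 -/- libraries and both the WT and het libraries. The higher genes were Anxa1, Ggh, Nr4a1, Rnf130, S100a6, Il33, Fabp5, Lgals3, Bace2 and Cd44, and the lower ones Fabp1, Adh1, Apoa4, Clic6, Rbp2, Apoc3, Cyp2d26, AI747448, Fbp1 and Aadac. Anxa1 was 8.18 CPM in WT, 11.8 in het, 115 in Bud and 1074 in Cys, and the fatty acid binding protein Fabp5 45.1, 15.9, 119.5 and 580.2. The beta-secretase relative Bace2 was 20.3, 29.8, 78.1 and 156, and the galectin Lgals3 31.5, 30.9, 85.0 and 185. Fabp1 was 615, 772, 1.67 and 1.81 in the same order. Of the 20 genes, 14 to 20 were chosen again under 8 alternatives. The rule takes WT and het as shared controls, so part of the sharing may come from the chance values of those libraries.

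Het organoids were higher than WT in genes of several differentiated cell types and lower in some DNA replication genes. Higher in het were 11 of 17 enterocyte genes (median log2 ratio 0.74, percentile 100), 11 of 12 tuft genes (median 0.86, percentile 100), 5 of 7 Paneth genes (median 1.14), 7 of 14 goblet genes with 1 lower (median 0.38) and 7 of 9 epithelial defence genes (median 0.63). S phase genes were lower in 4 of 16 (median -0.44, percentile 0), as were 2 of 16 G2 and M phase genes (median -0.29), although Mki67 was 264 CPM against 195. Lgr5 stood at 293 CPM against 278, and 2 of 14 stem cell genes were lower (median -0.15).

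Alpi was 3.58-fold higher in het (3.16 to 4.07), Sis 2.68-fold, the carboxylesterase Ces2a 6.34-fold (5.63 to 7.16) and the retinaldehyde dehydrogenase Aldh1a1 3.63-fold higher. The antimicrobial lectin Reg3g was 5.44-fold higher and Dmbt1 829.7 CPM against 319, and the matrix protease Mmp7 of Paneth cells 3.33-fold. The tuft cell ion channel Trpm5 was 4.77-fold and Rgs13 8.88-fold higher, with 34.1% of the Rgs13 UMIs in 1 het cell. Itln1 was 11.1-fold higher with 60.1% of its UMIs in 1 cell, and Ghrl reached 346 CPM with 87.6% in 1 cell. Fetal and regenerative genes were higher in 6 of 15, with Ly6a lower (median 0.40). Dissociation stress genes were higher in 8 of 13 and lower in 1 (median 0.56), with Egr1 3.93-fold and Fos 2.81-fold higher, beside 4 of 12 CREB/CRTC targets (median 0.14) and 6 of 14 ERK targets (median 0.28). Enteroendocrine genes had 4 higher and 2 lower of 13 (median -0.01), secretory progenitor genes 1 higher of 9 (median 0.21) and glycolysis 1 lower of 15 (median -0.26). The single MHC class II gene measured, H2-DMa, was 5.46 CPM against 1.73, called higher. Ifitm3 was 356-fold lower (121 to 1728), Trim44 17.7-fold (10.8 to 30.8), the desaturase Scd1 3.36-fold and the ribonucleotide reductase subunit Rrm2 2.21-fold lower, and Igf2bp3 was 0.228 CPM against 65.9. With equal weight for every cell, 6 rather than 11 enterocyte genes were higher, the log2 ratio of Aldh1a1 was 0.97 in place of 1.76, and 8 rather than 4 S phase genes were lower, and with no minimum count the Paneth median was 0.46. Het also had the largest share of wells rich in Kcnq1ot1, 17.1% (13.3 to 21.4) against 7.28% (4.62 to 10.8) in WT.

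Fetal organoids gave the reference for the fetal program. All 20 fetal and regenerative genes were higher than in WT (median 4.33, at the bound 6.27), as were 19 of 20 YAP/TAZ targets (median 2.32), 12 of 14 ERK targets (median 1.07), 11 of 13 p53 targets (median 1.52) and 7 of 12 hypoxia genes, of which 2 were lower (median 0.65). Enterocyte genes were lower in 16 of 17, with Krt20 higher (median -3.13), as were 10 of 14 stem cell genes (median -1.35), 15 of 16 S phase genes (median -0.94), 16 of 17 oxidative phosphorylation genes (median -0.70), 11 of 14 goblet genes (median -1.60) and 9 of 13 intestinal identity genes (median -1.78). Clu was 399-fold higher (295 to 554), Anxa1 243-fold (173 to 354) and Ly6a 143-fold. Spp1 (osteopontin) reached 1375 CPM with no UMI in WT, at least 1850.1-fold higher, fibronectin (Fn1) 756 CPM, at least 1016-fold, and Ankrd1 1025 CPM against 0.248. Gastric genes were higher in 6 of 8 (median 1.83), but Tff1 was 2.90 CPM and Gkn1 had no UMI. Lgr5 was 2.72-fold lower (2.46 to 3.01) and Cdx2 7.65-fold lower, and Smoc2 and Gata4 had no UMI, at least 610- and 337-fold lower. The tuft median of -0.35 became 2.24 when 50 UMIs were required, a value that can rest on very few genes. With equal weight per cell 10 rather than 16 oxidative phosphorylation genes were lower and the gastric median was 0.85, while with no minimum count it was 0.15.

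Across 7165 genes, the log2 ratio of Cys over het correlated with that of fetal over WT with r = 0.627 (covariance 0.660), and that of Bud over het with r = 0.0969 (covariance 0.0472). Of 530 genes at least 4-fold different between fetal and WT, 89.6% had the same sign in Cys and 60.2% in Bud. With both ratios taken against WT, r was 0.684 for Cys and 0.203 for Bud, while simulated libraries without any difference gave 0.573 and 0.551. The simulated ratios hold only counting noise, part of it shared through WT, so their r is no baseline for libraries that differ. For the real libraries with both ratios against WT, the covariances were 0.693 and 0.0802. The simulated covariance was 6.612e-03 for both. For Bud, r was 0.0845 to 0.203 over 4 alternatives.

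**Figure D3:**
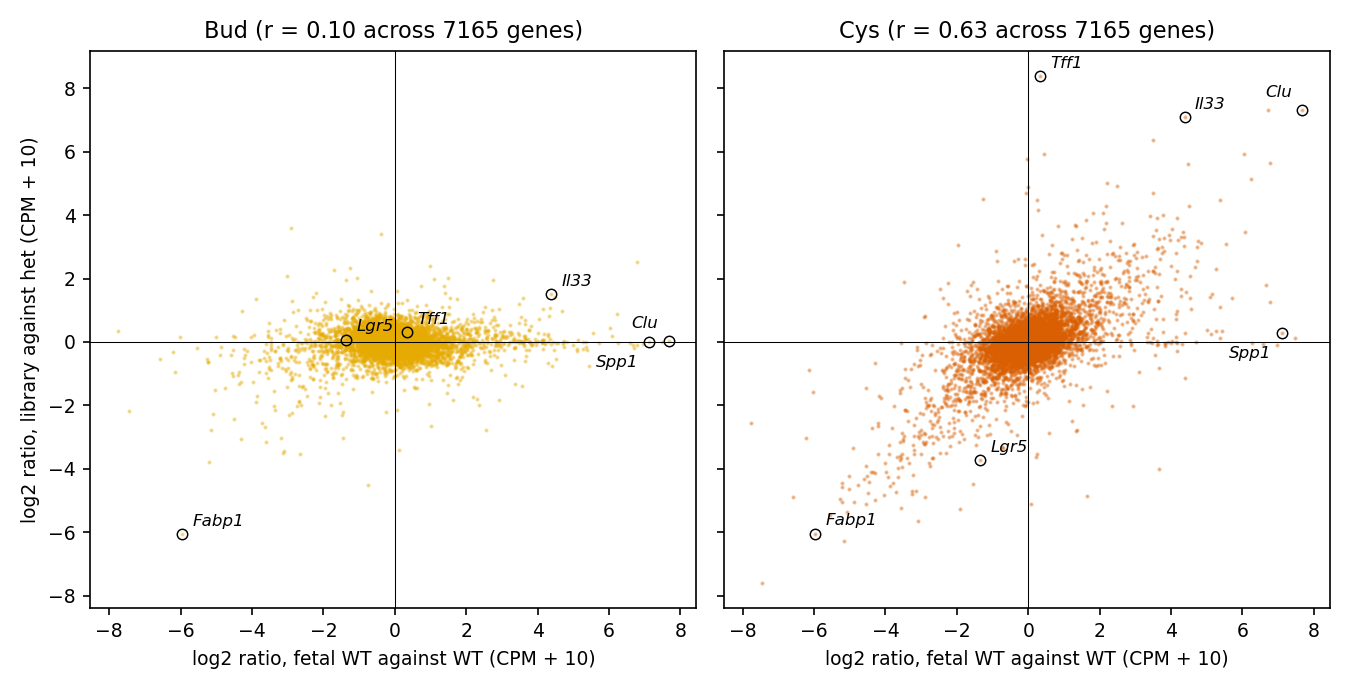
Each dot is 1 of 7165 genes, with the log2 ratio of fetal over WT on the horizontal axis and the log2 ratio of Bud over het or Cys over het on the vertical axis (10 CPM added). The cloud rises along the diagonal for Cys (r = 0.627) and is nearly level for Bud (r = 0.0969).

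Clustering of all cells gave 16 clusters. All 371 fetal cells and 337 of 359 Cys cells (93.9%, 90.9 to 96.1) lay in clusters made up to at least 90% of their own library, in each of the 4 clusterings tried, and since each library was its own plate such a cluster may be a plate and not a cell type. The other Cys cells lay in cluster 7 (5 cells) and cluster 9 (17 cells). These clusters had few UMIs per cell (medians 3333 and 2693.5) and much Kcnq1ot1 (16545 and 111151 CPM), so they may hold damaged cells. Cluster 9 held 4.97% of WT, 15.7% of het and 5.35% of Bud cells. WT, het and Bud cells mixed. The stem-like cluster held 21.5% of WT cells (17.0 to 26.6), 23.4% of het (19.0 to 28.1) and 18.9% of Bud cells (14.7 to 23.6), and the cycling cluster 18.9% (14.6 to 23.8), 13.7% (10.3 to 17.7) and 11.3% (8.06 to 15.3). Stem-like shares depended on the clustering, at 7.62% for WT, 21.4% for het and 11.01% for Bud at resolution 1.5 and at 32.1% for WT, 29.1% for het and 35.2% for Bud without cycle genes, and no cluster was named stem-like at resolution 0.5, whereas the cycling share was highest in WT among these 3 libraries in all 4 clusterings, although Mki67 had its highest level in het. After thinning, Lgr5 was found in 19.9% of WT, 17.9% of het, 29.6% of Bud, 1.67% of Cys and 10.8% of fetal cells, and without thinning in 68.9%, 54.1%, 71.1%, 11.7% and 51.5%. Enterocyte-, goblet- and enteroendocrine-like clusters were led by genes that themselves differed between libraries, so their sizes were not compared.

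**Figure D4:**
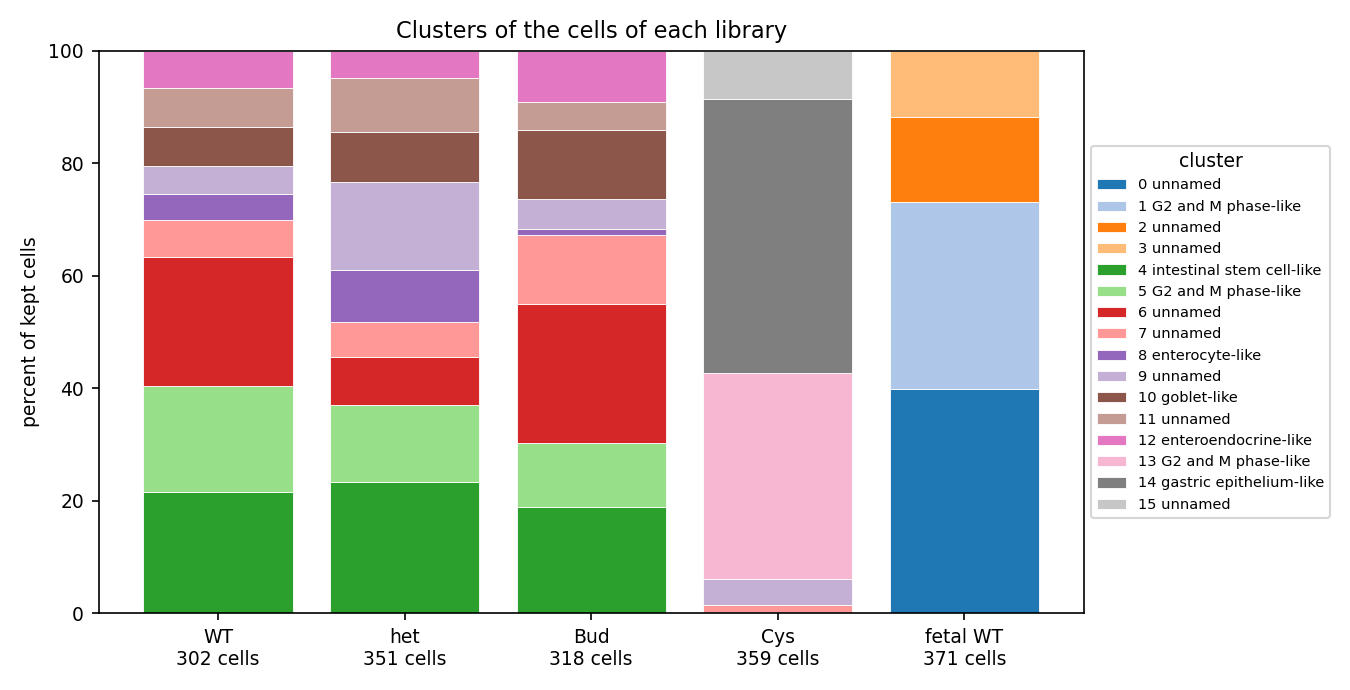
Percent of the kept cells of each library (stacked bars from 0) in each of the 16 clusters. WT, het and Bud share their clusters, whereas fetal and Cys cells fill clusters of their own, 337 of 359 cells in the case of Cys. The other Cys cells lay in clusters 7 and 9, which were low in UMIs and rich in Kcnq1ot1.

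Markers of other cell types were sparse. In Cys, the macrophage and lysosome gene Cd68 was 1 of 2 immune genes measured and higher (6.83 CPM against 2.23), the mesenchymal gene Postn was lower (0 against 2.97), and of the endothelial list the receptor Tek reached 333 CPM with no UMI in WT while Pecam1, Cdh5, Kdr and Plvap had none in Cys. In Bud and het no immune or mesenchymal gene was called. Cd68 was 24.9 CPM in fetal organoids, in which Ptprc, carried by blood cells, had 3 UMIs.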

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

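All tests of explanations in this part were chosen after the results were seen. Lists that went in opposite directions in the 2 Lkb1 -/- libraries drew attention first. The Paneth list had a median log2 ratio to WT of 0.64 in Bud and -1.54 in Cys, and the secretory progenitor list 0.46 in Bud and -0.74 in Cys. Against het, chosen as reference after seeing the data, the Paneth median was -0.59 in Bud and -2.10 in Cys, so that list then went the same way in both, while the secretory progenitor list stayed opposite at 0.30 and -0.50. The difference between Bud and Cys was not tested, since each is 1 library.

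The first pattern is the high level of fetal and gastric genes in Cys. Fetal organoid cells or their RNA in the Cys plate are argued against, because 64 genes that were abundant in fetal organoids and nearly absent from WT, het and Bud had a median Cys to fetal ratio of 0.0492 (quartiles 1.79e-03 to 0.279), against 0.608 for the fetal and regenerative list. The 2 very large wells are argued against as well, since without them the median of that list was 3.27, against 3.05 with them, and 19 of its genes were higher. An unrelated organoid line under the Cys label stays open. Of 7 genes at least 4-fold lower in both het and Bud than in WT, 71.4% were also lower in Cys (29.0 to 96.3), against 5.11% of other genes. That interval treats the genes as independent, which they are not. For Tph1, 1 of the 7, most of the WT UMIs lay in a single cell. WT may also itself be the line that stands apart. Loss of both Lkb1 copies as the cause could not be decided. With the labels taken as given, Bud, of the same genotype, had a median of 0.51 against 3.05 in Cys, so the level was not shared by both Lkb1 -/- libraries. In Cys against Bud, 18 of 20 fetal and regenerative genes and 11 of 12 gastric genes were higher. Whether the loss is the whole cause, part of it or none cannot be told apart from differences between lines or cultures, since each is 1 library.

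The second pattern is that Ifitm3, Igf2bp3 and Gas6 were near 0 in het, Bud and Cys and well expressed in WT, 3 genes singled out after their values were seen. Ifitm3 stood at 243 CPM in WT and 1026 in fetal organoids. Fetal cells or their RNA in the WT plate are argued against: 10 other genes abundant in fetal organoids and nearly absent from het and Bud had a median WT to fetal ratio of 0.0 and a highest of 3.23e-03, whereas that of Ifitm3 was 0.237. Whether the number of Lkb1 copies matters stays open, because of 15 genes of at least 20 CPM in WT and at least 10-fold lower in both Bud and Cys only these 3 were also 10-fold lower in het (median het to WT ratio 0.707), and a gene lost from 1 starting line would look the same. A difference between the WT line and the line that was edited may therefore account for them, a hypothesis that needs the origin of the lines.

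The third pattern is that Fabp1 and 9 other genes (1700030C10Rik, Chgb, Clic6, Fam111a, Fam149a, Fev, Pitx1, Rbp2 and Slc38a7) were nearly absent from Bud, also singled out after their values were seen. Over the whole libraries the other 16 enterocyte genes had Bud to WT ratios of 0.0264 to 0.697. Fabp1 (chromosome 6, 71199827 to 71205023, GRCm38) had one of 2.71e-03 (1.09e-03 to 5.60e-03), below the interval of the lowest, Rbp2 (9.60e-03 to 0.0585). Fabp1 was picked for its low value, so this rank is no evidence on fewer enterocytes. Fewer enterocytes as the whole cause is argued against for Fabp1 only by its low level within clusters, from few Bud cells. In the enterocyte-like cluster Fabp1 was not separated from Rbp2. In the enterocyte-like cluster, itself led by Fabp1, its ratio was 0.0138 (3.76e-03 to 0.0354) from 3 Bud and 14 WT cells, with a median of 1.36 for the other genes but 0.0427 for Rbp2, whose interval reaches down to 1.07e-03, and in the cluster led by Dmbt1 it had 0 UMIs in 16 Bud cells and 482 in 21 WT cells, with a median of 0.536, whereas the ratio of 3.21e-03 for both clusters together mixes clusters held in different shares. A deleted chromosome stretch that reaches the nearest expressed gene on each side, 3.50 to 2279 kb away, is argued against for the set, since these had a median ratio of 0.942. It stays open for Fam149a, whose left neighbour Cyp4v3 stood at 0.136 (0.0768 to 0.227), and deletions that end before the neighbours were not tested. In Cys, of the same genotype, 1700030C10Rik, Fam111a, Fam149a and Pitx1 stood at 47.8, 146, 73.3 and 24.7 CPM, against 24.5, 151, 42.6 and 24.5 in WT. Slc38a7 and Clic6 stood at 15.1 and 13.0, against 25.3 and 127. Fabp1, Chgb, Fev and Rbp2 were at most 1.81 CPM in Cys too. For part of the set, the near absence was thus not shared by both Lkb1 -/- libraries. An effect of Lkb1 loss was not tested, since each is 1 library.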

How the results depend on the processing

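The alternatives with het as reference, without wells above 100000 UMIs and without wells rich in Kcnq1ot1 were chosen after seeing the data, and the others before. No paired analysis was possible because the groups share only the replicate number 1, with 1 library each. The alternative without a mitochondrial cap was not run because the tables hold no mitochondrial genes. Other minimum counts were not run for single genes, whose ratios do not depend on that minimum, and genes named only as list members were examined through the counts and medians of their lists. Over 10 alternatives, 15 to 17 enterocyte genes were lower in Bud and in Cys, 9 to 10 stem cell genes were lower in Cys, and 6 to 11 enteroendocrine genes were lower in Bud. The Stk11 ratio to WT stayed at 0.524 to 0.589 in Bud, 0.330 to 0.470 in Cys and 0.684 to 0.731 in het. Of the values under alternatives fixed beforehand, 2039 list counts were within 1.5 times the first count and 131 were not, and 822 list medians moved by less than their interval and 125 by more. Another 3, of lists outside the middle 95% of random lists, changed sign, all with 50 UMIs required, and counting every list 28 medians did so. List counts of no genes in both runs were tallied as within, so part of the tally of counts could hardly change. Of the log2 ratios of named genes, 997 stayed within their interval and 227 did not, 159 of these with 1 CPM added and 61 with equal weight for every cell. The tallies were 91 and 89 for marker shares, 37 and 11 for cluster shares and 1 and 7 for fetal similarity.

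Against het, 7 rather than 11 fetal and regenerative genes were higher in Bud and 1 was lower, with a median of 0.18 inside the range of random lists. The Bud medians outside the middle 95% of random lists that changed sign against het were Paneth -0.59, goblet -0.028, M cell -0.062, ERK targets -0.24, epithelial defence -0.21 and dissociation stress -0.082, and those of Cys were S phase 0.019, goblet -0.30 and epithelial defence -0.10. Within that range, S phase 0.30, glycolysis 0.20, hypoxia 0.058, YAP/TAZ -0.047 and LKB1 complex -0.033 also changed sign in Bud, and G2 and M phase 0.028, ERK -0.012 and dissociation stress -0.088 in Cys. The log2 ratio in Bud became 0.57 for Erdr1, 0.0043 for Ifitm3, 0.16 for Igf2bp3 and -0.58 for Muc2, as het levels of these genes differed from WT levels. With equal weight for every cell, 6 rather than 11 enterocyte genes were higher in het, and the log2 ratio of Lyz1 in Bud was 1.44; the causes were not tested. When 50 UMIs were required, which leaves fewer genes in a list, the gastric median in Bud was -0.29 and the tuft median 1.89 in Cys and 2.24 in fetal organoids. No minimum number of genes was set for these medians, so they can rest on 1 gene. The tuft value in Cys equalled the log2 ratio of Avil, and these values do not show that a list reversed. With no minimum the gastric median was 0.15 in fetal organoids and the Paneth median 0.46 in het. The correlation with the fetal difference was 0.203 for Bud and 0.684 for Cys with both ratios against WT, 0.1475 and 0.659 with the WT cells split, and 0.188 and 0.676 over genes of at least 100 CPM. It was 0.607 for Cys over genes of at least 5 CPM. The cause of these movements was not tested. Depth limits low genes most: a gene with no UMI could stand at up to 0.511 (fetal) to 0.743 CPM (WT) by the floor of 3 UMIs.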

Other observations

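Some named genes outside the fixed lists also differed in Bud. The lipase cofactor Clps was 104.8 CPM against 15.6 in WT, 6.71-fold higher, the elastase Cela1 143 against 31.5, 4.55-fold higher (3.75 to 5.55), and the glutamate transporter Slc1a2 29.5 against 0.743, 39.7-fold higher (13.3 to 195). All 3 were also higher in Bud than in het, where they stood at 19.6, 21.8 and 0.228 CPM. In Cys, 6 of 14 genes of the unfolded protein response were higher, such as Sdf2l1 at 3.62-fold (2.78 to 4.77), Pdia6 at 2.34-fold and Calr at 1.94-fold, and 2 were lower, Atf4 and Trib3, while the growth arrest gene Gadd45a was 6.46-fold and the early response gene Jun 4.05-fold lower. The oxidase maturation factor Duoxa2 was 57.4 CPM in Cys and 1.49 in WT. Of 15 glycolysis genes in Cys, Hk1 and Slc2a1 were 3.17-fold and 1.78-fold higher and Pfkp was lower.

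Some genes of the fetal organoids were nearly absent from WT. Wfdc2 reached 1779 CPM, Igfbp7 1263, the chemokines Cxcl5 and Ppbp 1087 and 946.0, and the mucin Muc1 374, with at most 0.248 CPM in WT. The cyclin Ccnd1 was 5.36-fold and the growth factor Hbegf 12.5-fold higher in fetal organoids, against 2.65-fold and 2.87-fold in Cys. The galectin Lgals2 was 788-fold lower, the disaccharidase Mgam 117-fold and the metallothionein Mt2 98.9-fold lower. Car2, a carbonic anhydrase, stood at 20.3 CPM in WT, 3.87 in het, 3.57 in Bud, 1146 in Cys and 329 in fetal organoids, and the membrane protease Mmp14 at 24.0, 0.455, 0, 114 and 139 in the same order. Erdr1 was 4.46 CPM in WT, 166 in het, 252 in Bud and 1.00 in Cys, and these 3 genes were singled out after their values were seen. No explanation was tested for them.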
